A study of Caenorhabditis elegans with 2 samples.

How the data were processed

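Per the labels, the samples are ChIP-seq libraries from whole L1 larvae of mixed sex, made against eGFP-tagged NHR-11 from DNA fragments of 150 to 350 bp. They form 1 group of 2 biological replicates, so no comparison between groups was possible. The deposited files are peak lists in narrowPeak format, 4 on the ce10 build and 4 on ce11. On each build there are candidate peaks of replicate 1, of replicate 2 and of the pooled replicates, which served the authors as input to IDR, and an IDR-thresholded list. The aligner, the peak caller, their versions and the IDR threshold are not given in the sources used here, and neither is the extraction protocol. Per the deposited notes a further control file entered the peak calls; the control reads were not analysed here.

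The signal value of each peak is the authors' own, from their peak caller, and its scale is not given in the sources used here. It was used to rank, filter and describe peaks, and as paired values per called peak in the replicate correlation. Permutation tests also compared its medians between X and autosomal called peaks. The deposited -log10 q column reaches 3.16 in the called list and was not used for ranking, because it is at its ceiling for the strongest peaks. Candidate lists are long by design, with 30000 peaks in each replicate, and their lowest signal is 8.49 in replicate 1 and 7.14 in replicate 2. The 1141 called peaks on ce11 were exactly the pooled candidates with a signal of 49.9 or more, so a peak's place in the called set rests on the pooled signal, to which a strong replicate alone can contribute. There are 2 pairs of called peaks that share a start and differ in summit; each was kept. Read counts are not part of the lists, so depth is unknown and intervals below cover sampling of peaks only.

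Genes, transcripts and biotypes came from Ensembl release 115 on WBcel235, the assembly that ce11 names, with the RefSeq sequence of the same assembly; all ce11 peaks lay within its chromosome lengths. The ce10 lists were used only where no annotation was needed, and no coordinate was converted. Gene sets were matched by symbol: 97 symbols belong to more than 1 gene identifier among 19973 protein-coding genes. A promoter window ran from 1000 bp upstream to 200 bp downstream of any protein-coding transcript 5' end. Each summit received the first class that applied of promoter, 5' UTR, coding exon, 3' UTR, exon of a non-coding gene, intron and intergenic.

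The background for enrichment was the 27450 pooled candidates that overlap no called peak; the 136 other candidates that overlap a called peak were left out. Shares were compared with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment within classes, 27 gene lists, 18 motifs or 2080 words of 6 bases merged with their reverse complements, and a threshold of 0.05. For gene lists, 956 genes with a called summit in the promoter window were set against 7275 genes with only other candidate summits there. Motifs and words were sought on both strands within 50 bp of the summit. Intervals of shares are exact Clopper-Pearson intervals at 95%, and those of odds ratios are Woolf intervals. Replicate agreement was the share of called peaks that overlap by 1 bp or more a top candidate of each replicate, against 1000 circular shifts, and the correlation used 100000 permuted pairings. Tests, gene lists, motifs, the naming rule and most alternatives were fixed before the data were examined.

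The naming rule took nhr-11 and unc-119, the genes at the 10 strongest called peaks, and the strongest called members of each list, up to 4 for a list past the threshold and up to 2 for the others in order of p, to 30 genes in all. Alternatives changed the overlap rule, the promoter window, the background, the summit position, the sequence window and the class order, kept only the 570 strongest called peaks, left out the transgene loci, or replaced the called set by the 1141 strongest candidates of either replicate alone. GC-matched candidates were drawn within 10 GC classes to the composition of the called windows.

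The tests were run on simulated data before use, with called sets drawn from the 28727 pooled candidates. Without a planted effect, 5 of 60 single tests, 2 of 540 list tests, 0 of 360 motif tests, 4 of 10400 word tests and 1 of 10 rank correlations passed the threshold. Planted enrichments of promoters, of the ribosomal protein list and of a word were found in 5 of 5 draws each, and a planted rank correlation over 1141 values in 3 of 3. The rank correlations used simulated pairs of values without selection by pooled signal. They therefore do not check that test on a set chosen as the called peaks were. Promoter odds planted at 4 came out at 3.81 to 4.74 when planted alone and at 4.40 to 4.94 with the ribosomal protein list planted as well. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.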

Results

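Chromatin immunoprecipitation and sequencing (ChIP-seq) was used to map the genomic regions associated with NHR-11, a nuclear hormone receptor of Caenorhabditis elegans, in whole larvae of the L1 stage, the stage that hatches from the egg. The strain carried an integrated transgene with NHR-11 fused to eGFP in an unc-119 mutant background, where unc-119, a gene needed for nervous system function, serves as the rescue marker. There was 1 group of 2 biological replicates, with no second genotype, stage or untagged strain, so the comparisons are between called regions and the other candidate regions of the same experiment. Each replicate had a list of 30000 candidate peaks, the pool of both had 28727, and 1141 of the pooled peaks formed the set the authors called reproducible by IDR (irreproducible discovery rate), all on the ce11 build. The files hold no read counts, so the sequencing depth is unknown, and p-values below measure variation across peaks or genes within 1 experiment, not between animals.

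The replicates placed most of their strongest candidates at the same regions. Of the 1141 highest-signal candidates of replicate 1, 746 (65.4%, exact Clopper-Pearson 95% interval 62.5 to 68.1%) overlapped one of the 1141 highest of replicate 2, where circular shifts gave at most 1.75%; this comparison, added after the data were seen, does not involve the pooled list. Of the 1141 called peaks, 742 (65.0%, exact interval 62.2 to 67.8%) overlapped one of the 1141 highest-signal candidates in each replicate, where circular shifts along the chromosomes gave a mean of 0.469% and at most 1.14% in 1000 shifts; the called set was chosen by the pooled signal of the same replicates, which the shifts do not take into account. A further 188 were among the top candidates of replicate 1 only, 179 of replicate 2 only and 32 of neither. The median pooled signal was 95.3 for the shared peaks and 57.3, 56.1 and 51.9 for the other classes, an order that the pooling of the same replicates largely fixes. When any candidate was allowed, 1137 of 1141 had an overlapping candidate in both lists. Across these 1137 peaks the signals of the replicates correlated with Spearman's rho of 0.622 and Pearson's r of 0.720 on log10 signal, and each permutation p was 1e-05, the smallest that 100000 pairings can give (two-sided). Without the 2 peaks farthest from the median in replicate 1, r was 0.714. These are correlations across peaks of 1 experiment, and neighbouring peaks are not independent. The permuted pairings, like the shifts, do not take into account that the called set was chosen by the pooled signal.

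**Figure D1:**
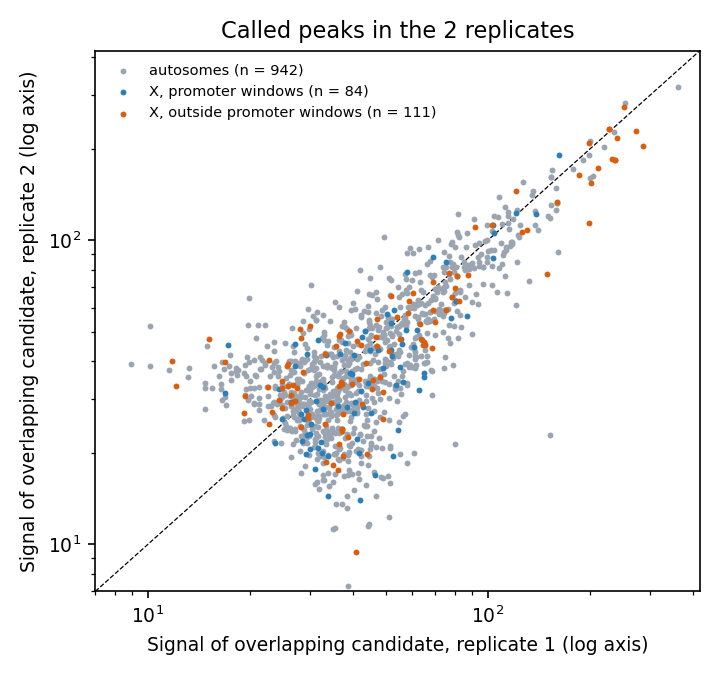
Signal of the strongest overlapping candidate peak in replicate 1 (x axis) and replicate 2 (y axis), both on log axes in the authors' signal units, for 1137 called peaks, with autosomal peaks in grey, X peaks in promoter windows in blue and other X peaks in orange; the dashed line marks equal values. Points scatter widely at low signal and lie closer to the line at high signal, where several X peaks outside promoter windows sit. Peaks were called by pooled signal, so pairs low in both replicates are left out, which by itself shapes the scatter at low signal.

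Of the 10 strongest called peaks, 2 lay in promoter windows, 6 on the X chromosome outside promoter windows and 2 in introns of autosomal genes. The highest signal, 681, belonged to a peak at chromosome II 10563443 to 10563717 (ce11), 177 bp from the 5' end of cdc-48.1 (WBGene00007352), which encodes an AAA ATPase that extracts ubiquitinated proteins. Its signal was 363 in replicate 1 and 319 in replicate 2. The next, with a signal of 536, had its summit at III 3867572, 282 bp from the 5' end of rpl-3, a gene for a protein of the large ribosomal subunit. The genomic sequence around that summit, from 3867552 to 3867592, read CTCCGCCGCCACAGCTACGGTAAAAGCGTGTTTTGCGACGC.

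The X peaks among these 10 had pooled signals from 424 to 531. Their summits at X 11094176, 12363198, 9465875 and 13700821 were intergenic, and the nearest protein-coding 5' ends were those of W02H3.3 at 4010 bp, F19H6.5 at 1706 bp, ZK899.6 at 2530 bp and K02D3.1 at 6086 bp. The summit at X 6296550 lay in an intron of mom-1, which encodes the Porcupine protein needed for Wnt secretion, with a signal of 227 in replicate 1 and 232 in replicate 2. The summit at X 2997112 lay in an intron of Y41G9A.17. The sequence from X 2997092 to 2997132 was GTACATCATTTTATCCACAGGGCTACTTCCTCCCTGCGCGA. The 2 autosomal intron peaks were at II 10552129 in mnk-1, a MAP kinase-interacting kinase gene, with a signal of 473, and at II 9603617 in nhr-19, itself a nuclear hormone receptor gene, with a signal of 418.

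Called peaks lay at promoters more often than the other candidates did. A summit fell between 1000 bp upstream and 200 bp downstream of a protein-coding 5' end for 708 of 1141 called peaks (62.1%, 95% interval 59.2 to 64.9%) and for 8469 of 27450 other pooled candidates (30.9%, 30.3 to 31.4%), an odds ratio of 3.66 (Fisher's exact test, two-sided, p = 1.28e-99). Promoter windows cover 26.2% of the genome. By rank of pooled signal the share was 61.8% for ranks 1 to 285, 67.7% for ranks 286 to 570, 60.7% for ranks 571 to 855, 58.0% for ranks 856 to 1141, 50.7% for ranks 1142 to 2282 and 28.5% beyond rank 11410. Against the 1141 candidates ranked next below the called set the odds ratio was 1.59.

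Called summits were rarer than other candidates in coding exons, 3' UTRs and introns. Coding exons held 6 called summits (0.526%) and 10.4% of the other candidates, an odds ratio of 0.0453, and 3' UTRs held 0.789% against 3.48% (odds ratio 0.221, but 0.465 with the top candidates of replicate 1 alone). Introns held 11.8% of called summits and 28.2% of the others (odds ratio 0.341), with adjusted p of 1.28e-43 for coding exons, 2.07e-08 for 3' UTRs and 5.08e-39 for introns (Fisher's exact test, Benjamini-Hochberg over 7 classes). The 5' UTR share was 0.526% against 0.466%, exact adjusted p = 0.659, and exons of non-coding genes held 2.98% against 2.09%, adjusted p = 0.054. Both classes depended on the order of assignment: with gene features ranked before promoter, called peaks had the higher share of 5' UTR summits (3.68% against 1.75%, exact adjusted p = 2.46e-05) and of non-coding exon summits (7.71% against 2.83%, exact adjusted p = 2.17e-15). Intergenic summits made up 21.3% of called peaks and 24.4% of other candidates, exact adjusted p = 0.0211; this difference did not pass when the top candidates of either replicate alone took the place of the called set, with odds ratios of 0.962 and 0.870.

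**Figure D2:**
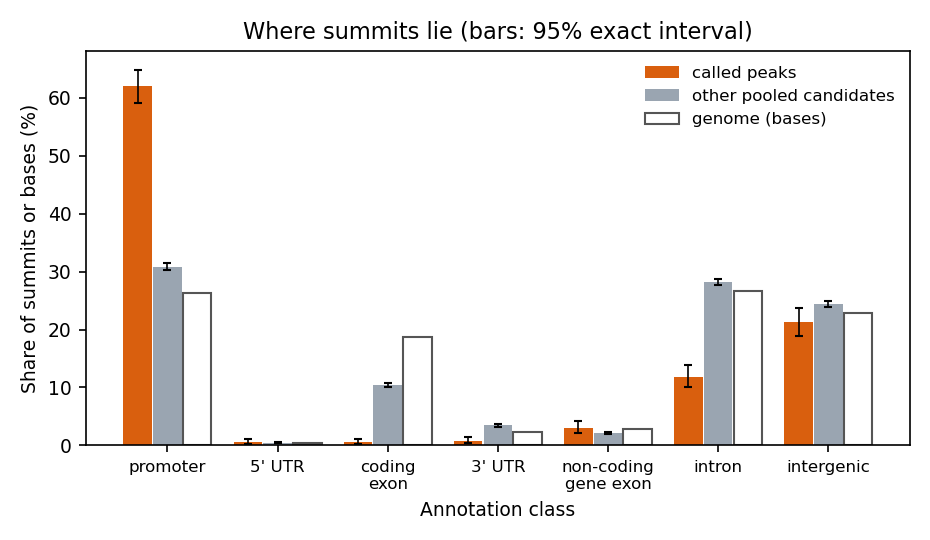
Share of summits (y axis, percent) in each annotation class (x axis) for 1141 called peaks (orange) and 27450 other pooled candidates (grey), with exact 95% intervals as error bars, beside the share of genome bases in the class (white). Promoters held 62.1% of called summits and 30.9% of the others, and coding exons 0.526% and 10.4%.

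The genes beside called peaks were enriched for the protein synthesis machinery. Of 75 ribosomal protein genes with any candidate summit in the promoter window, 43 had a called summit (57.3%), against 11.6% of all 8231 genes tested. The odds ratio was 10.7 (95% interval 6.71 to 16.9, adjusted p = 2.79e-20, Fisher's exact test with Benjamini-Hochberg adjustment over 27 lists). The strongest members after rpl-3 were rpl-20 with a signal of 373, rpl-35 with 361 and rpl-15 with 254. Translation factors had 9 of 28 genes called (odds ratio 3.63, exact adjusted p = 0.0296). They included eef-2, the elongation factor for translocation, with a summit at I 9163520, 11 bp from its 5' end, and a signal of 248; iff-2, an eIF5A gene, with 211; eif-3.C with 208; and eef-1A.1, which delivers aminoacyl-tRNA to the ribosome, with 170. Genes of mitochondrial respiration had 11 of 33 called (odds ratio 3.84, exact adjusted p = 0.0114), led by cox-5A (signal 219), the ATP synthase gene atp-1 (113), the succinate dehydrogenase gene mev-1 (81.5) and the complex III gene cyc-1 (76.7). The respiration call was lost with replicate 2 alone (odds ratio 2.44, exact adjusted p = 0.143), with replicate 1 alone (2.79, 0.119) and among the stronger 570 called peaks (2.59, 0.474). The translation factor call was lost with a promoter window of 500 bp upstream and 0 bp downstream (odds ratio 2.98, exact adjusted p = 0.132). Against candidates matched for GC content, a comparison added after the data were seen, only the ribosomal list passed, with an odds ratio of 6.60. Translation factors kept an odds ratio of 3.68 there (interval 1.13 to 11.98, exact adjusted p = 0.448) with 13 of the 28 genes left in the test, and respiration fell to 1.80 (interval 0.760 to 4.25, 0.549). Against the 1141 candidates ranked next below the called set the ribosomal list again passed alone, with 3.23, and the odds ratios were 1.09 for translation factors and 1.61 for respiration.

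The other 24 lists did not pass as tested. Splicing factors had 7 of 22 genes called (exact adjusted p = 0.0666), with snr-4 at a signal of 128 and prp-19 at 105. This list did pass against all protein-coding genes (exact adjusted p = 0.00376), with peaks counted singly (0.0115), with a promoter window of 2000 bp upstream and 500 bp downstream (0.00878) and with replicate 1 alone (0.00207). Stress and heat shock genes had 5 of 17 (exact adjusted p = 0.177), among them the chaperone genes hsp-1 (250) and hsp-90 (237); they passed among the stronger 570 called peaks (adjusted p = 0.0293). Histone genes had 3 of 9 called (exact adjusted p = 0.207) and proteasome genes 5 of 26 (0.411), and both lists passed with replicate 2 alone, at 0.00292 and 0.0068. Cell cycle genes had 4 of 13 (exact adjusted p = 0.207), with pcn-1, the PCNA gene, at 178 and the E2F gene efl-1 at 114. Neuropeptide genes had 1 of 51 called, ins-39, with a signal of 217 (odds ratio 0.151, exact adjusted p = 0.141). Nuclear hormone receptor genes had 13 of 142 called (odds ratio 0.764, interval 0.43 to 1.36, exact adjusted p = 0.55). Marker lists describe genes beside called regions and not the cells that were bound: muscle markers had 3 of 26 called, neuron markers 3 of 20, germline markers 2 of 5, and intestine, pharynx and epidermis markers 0 of 8, 0 of 7 and 0 of 14, all with adjusted p of 0.22 or more.

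**Figure D3:**
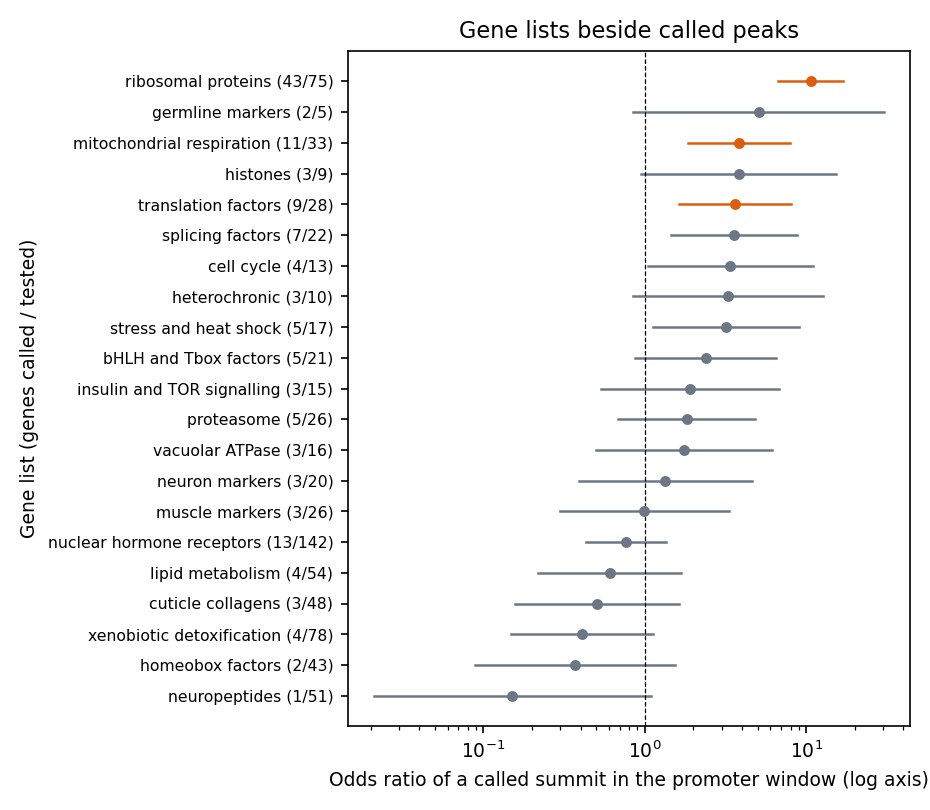
Odds ratio (x axis, log) of a called rather than another candidate summit in the promoter window for each gene list with a called member (y axis, with genes called and genes tested), and its 95% interval as a line. Orange marks adjusted p under 0.05, which the ribosomal protein, mitochondrial respiration and translation factor lists reached; the dashed line is an odds ratio of 1.

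Small non-coding RNA genes were also nearer to called peaks. A tRNA, snRNA, snoRNA or rRNA gene lay within 500 bp of 58 called summits (5.08%, interval 3.88 to 6.52%) and 523 other candidates (1.91%), an odds ratio of 2.76 (Fisher's exact test, p = 2.13e-10). Against only the 1141 candidates ranked next below the called set the odds ratio was 0.982 (exact p = 1), so called peaks and the next-ranked candidates did not differ detectably.

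The sequence under called summits differed from that of other candidates. Motifs and words were not compared with the candidates ranked next below the called set. It thus stays open whether the differences belong to strong candidates in general. Windows of 50 bp to either side had a median GC content of 45.5% in called peaks and 32.7% in the others. Of 18 motifs, 7 were more frequent in called windows and 6 less frequent after adjustment. Against GC-matched candidates the numbers were 6 and 3, and the 6 include the pharyngeal forkhead site, which did not differ from the other candidates (odds ratio 0.975, exact adjusted p = 0.763) but did from the matched ones (1.39, 0.000144). The GAGA repeat (GAGAGA) occurred in 30.6% of called windows and 7.4% of the others (odds ratio 5.52, exact adjusted p = 1.71e-109). The odds ratio was 2.77 against GC-matched candidates. Its frequency peaked at the summit: 10.3% of called peaks held it in the 20-bp bin just before the summit. In bins centred 490 and 470 bp away it was 1.4% and 1.67% before the summit, and 0.526% and 1.84% after it. The E2F sequence (8.76% against 3.26%) and the E-box CACGTG (5.61% against 1.78%) were also more frequent, with exact adjusted p of 1e-16 and 9.22e-14. Their odds ratios of 2.85 and 3.28 were 1.44 and 1.88 against GC-matched candidates. The C/EBP type site was rare (1.49% against 0.339%, odds ratio 4.45). It had the largest odds ratio of the 18 motifs against GC-matched candidates, 3.56 (exact adjusted p = 0.000994). T blocks (4.12% against 16.8%), the splice acceptor sequence TTTTCAG (2.80% against 10.7%), homeodomain sites (2.28% against 5.83%) and GATA sites (5.35% against 9.38%) were less frequent. The heat shock element was less frequent too (3.24% against 7.31%). Against GC-matched candidates T blocks, the splice acceptor and the heat shock element remained less frequent, with odds ratios of 0.659, 0.403 and 0.614. Homeodomain and GATA sites no longer passed, with 0.930 (exact adjusted p = 0.877) and 0.916 (0.692), and neither did the E-box CAGCTG (1.39, 0.0714) and the GC box (0.989, adjusted p = 1).

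Among sequences that nuclear receptors are known to bind, AGGTCA did not differ detectably, at 2.45% of called windows and 2.32% of the others (odds ratio 1.06, interval 0.722 to 1.55, exact adjusted p = 0.763), nor against GC-matched candidates, where the odds ratio was 0.688 (adjusted p = 0.114). AGTGCA was more frequent (6.13% against 3.29%, odds ratio 1.92, exact adjusted p = 3.59e-06), with 1.49 and 0.0189 against GC-matched candidates. AAGTCA was less frequent (3.07% against 4.42%, odds ratio 0.685, exact adjusted p = 0.0366), but the AAGTCA difference passed in only some settings. It did not pass against GC-matched candidates (odds ratio 0.859, exact adjusted p = 0.559), among promoter peaks (0.753, 0.297) or among the stronger 570 (0.666, 0.166). Nor did it pass without ribosomal protein promoters (0.711, 0.0695), with replicate 2 alone (0.700, 0.0537) or with replicate 1 alone (0.750, 0.123). It passed against windows shifted by 500 bp (0.564, exact McNemar test, adjusted p = 0.0190) and in windows of 100 bp (0.760, exact adjusted p = 0.0293). The odds ratio thus stayed below 1 and lay nearest 1 against GC-matched candidates. Of 2080 words of 6 bases, 679 were more frequent and 414 less frequent. Against GC-matched candidates the numbers were 214 and 282. Words that overlap within 1 longer sequence are counted separately here, so these are not counts of separate motifs. An example is GACGCA and ACGCAG, the second with an odds ratio of 8.34 against all other candidates. By p-value GAGAGA came first and GACGCA next, and GACGCA had the larger odds ratio: it occurred in 19.6% of called windows and 2.80% of the others (odds ratio 8.48, exact adjusted p = 3.04e-103), and against 4251 GC-matched candidates in 19.6% and 6.61% (odds ratio 3.45, adjusted p = 3.63e-32).

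**Figure D4:**
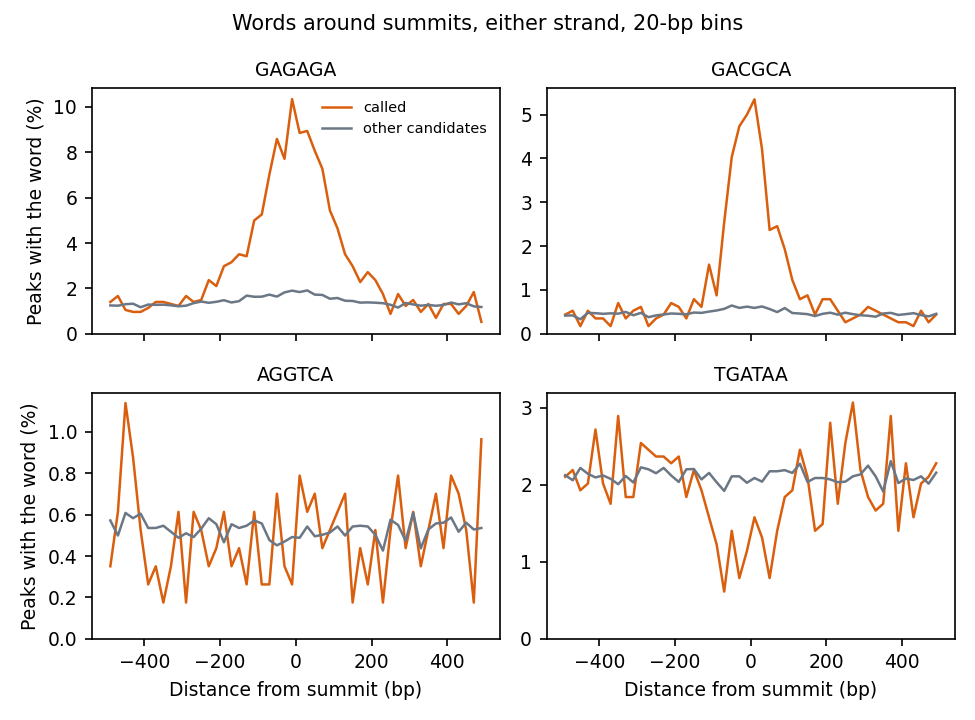
Percent of called peaks (orange, n = 1141) and other pooled candidates (grey, n = 27450) with each word on either strand (y axis) in 20-bp bins by distance from the summit (x axis, bp). GAGAGA and GACGCA peaked at called summits, at 10.3% and 5.35% of peaks per bin, AGGTCA stayed under 1.2% in every bin, and TGATAA, the GATA site, dipped near called summits, a difference that did not pass against GC-matched candidates.

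The X chromosome, which is subject to dosage compensation in worms, held 195 called peaks (17.1%, interval 14.9 to 19.4%) and 5322 of the other candidates (19.4%). The odds ratio was 0.857 (interval 0.733 to 1.00, Fisher's exact test, p = 0.0556), so the share did not pass the threshold. With the top 1141 candidates of replicate 2 alone in place of the called set the odds ratio was 0.824 (exact p = 0.0151), and with those of replicate 1 alone 0.832 (exact p = 0.0236), both past it. It lay nearer 1 among the stronger 570 called peaks (0.983, exact p = 0.915), by chromosome length (0.960, p = 0.641) and against the next-ranked candidates (0.909, p = 0.412). The density of called peaks ranged from 9.37 per Mb on IV to 13.9 per Mb on III, with X in between. Outside promoter windows alone, a setting chosen after the data were seen, the X share was higher in called peaks (odds ratio 1.29, exact p = 0.0236).

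The transgene loci differed from each other. Within 5 kb of nhr-11 (WBGene00003610, IV 9070003 to 9073622, plus strand) there was no called peak and no candidate in replicate 1, replicate 2 or the pool. The gap in which no list had a candidate ran from IV 9041442 to 9087661. It holds 6 protein-coding genes, named here after the gap was seen: besides nhr-11 these are Y73F4A.2, Y73F4A.1, mppb-1, mans-4 and twk-8. At unc-119 (WBGene00006843, III 10902641 to 10908935) there was 1 called peak, in an intron, with its summit at III 10903462, a pooled signal of 83.1 and rank 465 of 1141. Whether extra copies of this rescue marker on the transgene contributed to the peak was not tested.

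**Figure D5:**
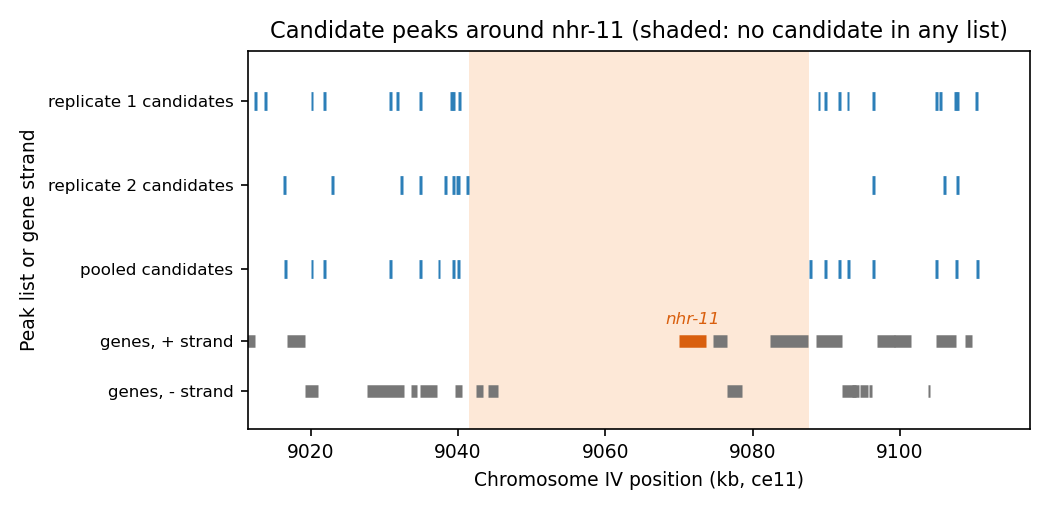
Map of chromosome IV around nhr-11 (x axis, kb on ce11) with the candidate peaks of replicate 1, replicate 2 and the pool as blue marks and protein-coding genes by strand as bars (y axis). The shaded interval from 9041442 to 9087661 holds no candidate in any list, and nhr-11 is drawn in orange.

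The same experiment on the older ce10 build gave 1110 called peaks and 27761 pooled candidates, against 1141 and 28727 on ce11, a ratio of 1.03 for called peaks. Called peaks on X numbered 189 and 195, and on each autosome ce11 had between 3 and 6 more than ce10. At or above the median signal of the ce11 set there were 573 peaks on ce10 and 571 on ce11.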

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

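The alternatives that used GC-matched lists, the replicates' top candidates against each other, next-ranked candidates for gene lists, repeated symbols, ribosomal protein promoters, peaks outside promoters or the autosomes alone were chosen after the data were seen. Over 386 recomputed values, 352 kept their direction and their side of the threshold or stayed within error. Most of these values belong to lists, motifs and classes that had passed, to the words with the lowest p and to the named genes. They were thus picked for strength in the same data, and named genes alone gave 82 of 84 unchanged values. A list, motif or class that passed only under an alternative was not by itself scored as a change. The count is therefore no measure of robustness for the results as a whole. The promoter share passed under each of its 10 alternatives, with odds ratios from 1.59 to 5.31, and the replicate correlation under each of its 5, with rho from 0.499 to 0.697. Replicate overlap moved to 54.3% with 50% reciprocal overlap, to 88.96% with the 2282 strongest candidates of each replicate and to 74.0% for the 570 strongest called peaks; the first 2 follow from a stricter and a looser rule, and the cause of the last was not tested. The small RNA gene odds ratio fell below 1, to 0.982, against the next-ranked candidates, and that of the GC box to 0.989 against GC-matched candidates; the second follows from the matching, and the cause of the first was not tested. The X odds ratio turned to 1.29 outside promoters and ranged from 0.824 to 0.832 without replicate 1 or 2; the cause was not tested. Only 1 list passed against GC-matched candidates and 1 against the next-ranked, where 3 had passed; the translation factor odds ratio of 3.63 was 3.68 and 1.09 there, the first lost with fewer genes in the test (13 of 28). In all, 496 words passed against GC-matched candidates where 1093 had. No setting without a replicate exists for the replicate overlap and correlation, which need both. No paired analysis was possible because there is 1 group. Depth is unknown, which leaves open whether peaks called from 1 strong replicate reflect uneven sequencing.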

Other observations

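The tests in this part were chosen after the results were seen, except the comparison of the recruitment motif between X and autosomal called peaks and that of GC content on X, whose outcomes were set down beforehand. By gene type, the small RNA genes more frequent near called peaks than near all other candidates were those for snRNA, the RNA parts of the spliceosome, and snoRNA, which guide RNA modification. An snRNA gene lay within 500 bp of 15 called summits (1.31%) and 37 other candidates (0.135%), an odds ratio of 9.87 (interval 5.4 to 18.04, Fisher's exact test, adjusted p = 4.24e-09 over 4 types). For snoRNA genes the numbers were 28 and 188 (odds ratio 3.65, exact adjusted p = 8.97e-08). For tRNA genes they were 16 and 299 (odds ratio 1.29, interval 0.778 to 2.14, exact adjusted p = 0.412), and no called peak lay near an rRNA gene, against 1 other candidate. Against only the 1141 candidates ranked next below the called set, of which 9 and 25 lay near such genes, neither type differed detectably, with odds ratios of 1.68 for snRNA (interval 0.730 to 3.84, exact adjusted p = 0.61) and 1.12 for snoRNA genes (interval 0.651 to 1.94, exact adjusted p = 1), which leaves open whether the excess belongs to strong candidates in general.

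X peaks outside promoter windows were frequent at the top of the called set. Among the 25 strongest called peaks 13 were on X, 12 of them outside promoter windows, against 25 on X among the strongest 100 and 195 among 1141. Outside promoter windows the median signal was 81.1 for 111 X peaks and 69.9 for 322 autosomal peaks (permutation p = 0.0135), and within promoter windows it was 75.7 for 84 X peaks and 75.6 for 624 autosomal peaks (permutation p = 0.99).

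A candidate explanation for the strong X peaks outside promoters is that they are recruitment sites of the dosage compensation complex, which binds motif-bearing sites on X and spreads from them. The core of that motif, GCGCAGGG, lay within 100 bp of 11 of the 111 X summits and of 2 of the 322 autosomal ones. The odds ratio was 17.6 (interval 3.84 to 80.7, Fisher's exact test, p = 1.02e-05). Among other X candidates outside promoters, which were not matched for GC content, it lay near 6 of 3995. Of the called X summits outside promoters, 8 of the 15 within the strongest 50 and 3 of the other 96 had it nearby. In promoter windows it lay near 3 of 84 called X summits and 0 of 624 autosomal ones, so it was not confined to peaks outside promoters. As an account of the higher median on X, GC content alone is only weakly argued against. The log2 ratio of X over autosomal median signals averaged 0.18 over GC quartiles (permutation p = 0.0447). It was above 0 in each of the 4, as set down beforehand, although only 0.0039 in the lowest. Medians over all 111 and 322 peaks do not test whether GC content accounts for the strongest X peaks. Whether NHR-11 binds these sites, or they are recovered in any ChIP from such larvae, stays open, since no untagged or unrelated ChIP was analysed here.

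The absence of candidates around nhr-11 itself, the tagged gene, was unusual in length. The gap common to the lists spanned 46.2 kb, rank 7 by length among 46900 gaps with a median of 997 bp, and chance spacing is argued against, since only 0.436% of protein-coding genes lay in a gap as long. By list the gap was 47.4 kb in the pool, 48.5 kb in replicate 1 and 54.8 kb in replicate 2. By bounds set after the gap was seen but before the share below was known, repetitive sequence was neither favoured nor argued against. The share of 32-base words that occur only 1 time in the genome was 76.3% in the gap and 89.8% on the chromosome, and at most 18.5% in the 6 longer gaps. A ranking by such positions, added as a criterion after the share was seen, argues against repetitive sequence as the whole cause. By it the gap ranked 1 in the genome, with 35.2 kb of such positions. The next, on chromosome II, had 32.4 kb and lay away from nhr-11 and unc-119. For extra copies of the region on the transgene, the criterion was a block no longer than a cloned insert in every list, written after the gap was seen. The gap of replicate 2 exceeded the length allowed. A gap between spaced candidates can run past the ends of such a block, so this excess does not decide the question. Such copies, which could raise the control as much as the ChIP or lead to its exclusion from peak calling, remain open, because no read-level track was analysed here. The missing peaks therefore say nothing on whether NHR-11 binds its own gene.

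The ribosomal protein genes beside called peaks could reflect sequence composition, raised ChIP background at very active genes, or binding by NHR-11. GC content is argued against as the whole source: the odds ratio fell from 10.7 to 6.60 against GC-matched candidates (3.23 against the next-ranked ones) but kept an exact adjusted p of 1.35e-08. If active genes in general gave background, other abundantly transcribed loci should be called too: outside protein-coding promoters the odds ratio was 4.60 for snRNA and snoRNA genes (interval 2.73 to 7.76) but 1.78 for tRNA genes (interval 0.907 to 3.48), both against all other candidates and not the next-ranked ones, and no transcript levels were analysed here. Background of this kind and binding cannot be told apart, as the control and other factors' ChIP were not analysed here. For this pattern no biological explanation was tested.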
